A study of Mus musculus with 4 samples.

How the data were processed

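Poly(A) RNA of mouse NRAS/AE9a leukemia cells was bisulfite-converted and sequenced as 4 libraries, 2 WT and 2 Tet2 KO, per the labels. Cells grew in medium with SCF at 50 ng/ml, IL-3 and IL-6 at 10 ng/ml, G418 at 1 mg/ml and puromycin at 2 µg/ml, per the labels' protocols. Libraries were made with a stranded mRNA kit, per the labels, and the design text plans 70000000 single-end reads per sample. Groups were taken from the genotype label. The genome build mm10 comes from the submitters' processing notes. The aligner, the site caller and their versions are not given in the sources used here.

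The deposited table holds one line per position, and by its name lists significant, annotated sites unique to the KO. The read numbers in it, of reads covering a site and of unconverted cytosines, are not normalized, per the file headers and the values; they are the reads of 1 library where 1 replicate made the call, and elsewhere a score, the mean of both KO libraries rounded by the authors to a whole number. The authors' methylation level is a fraction, the unconverted reads over the reads used at the site, averaged over the KO replicates that made the call. The number of KO replicates with a call, 1 or 2, is a deposited column of its own. A normalized coverage, whose scaling factor is not given in the sources used here, was deposited too and was not used. The combined p-values are the authors' own, and in the authors' deposited table the highest was 0.000114 for the methylation state and 0.0773 for the rate. There were 0 columns of samples from another series. At sites with 1 call the level gave a whole number of reads used in 100% of cases (tolerance 0.0006), at least 10 reads and a median of 82.6% of the covering reads. What sets the covering reads outside the level apart is not given in the sources used here. The deposited SD was read as the population SD, since 78.5% of 47139 sites then gave whole reads for both replicates against 10.5% with the other divisor (tolerance 0.0012). Printed SDs were converted to sample SDs.

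The tests, gene lists and the rule for named genes were fixed before the data were examined. The planned test of KO against WT, the tests between single replicates and the sequence context were not made, because the table used here has no WT or single-library values and no genome was used here. With no exon annotation used here, location was taken as the decile of the RefSeq gene span, in place of the planned transcript features, and the rule's limit to annotated exons was dropped. Gene names came from the table's labels, of which 7806 of 7821 matched a RefSeq symbol, 7538 of them directly, and 99.5% of pairs of a site and a gene label lay inside the span of the gene. Coverage of at least 10 reads was required. Wilson intervals at 95% were given for levels from 1 replicate and Clopper-Pearson intervals for shares; both cover counting error only.

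Each gene list was tested with a two-sided Fisher's exact test against the other protein-coding genes, with Benjamini-Hochberg adjustment over 16 lists at 0.05. A list of mitochondrial genome genes had no member in this background and was not tested; the mitochondrial genome held 128 sites, 0 of them with a gene label. Levels of a list were set against 10000 random lists matched on 5 bins of coverage, using genes with 5 or more sites. The p from matched lists was 2 times the smaller tail of the percentile, a step added after the percentiles were seen. Counting noise between replicates was computed from the binomial variance at the reads used. Spike-in and other sites were compared at equal coverage, with 2000 bootstrap resamples of spike-in sequences. Runs were defined by another listed site within 10 nt on the same strand.

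Named were the 10 sites with the highest level at 50 or more covering reads, 1 per gene, the 10 genes with the most sites, the 3 members of each list with the highest site at 20 or more covering reads, and always Tet2, Tspan13, Cxcr4, Ybx1, Nsun2, Alyref and Mbd6. Ties went to the higher coverage. Some genes that this rule names are not reported here. Pancreatic hormone genes, 6 lists of tissue markers (endocrine and exocrine pancreas, liver, brain, muscle and heart, kidney and intestine), and minus-strand genes were added after the data were examined.

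Tests were checked on simulated data. On 21900 genes, the list test called 96.5% of lists of 30 genes planted with a share of sites of 70% against 34%, and 1.5% of lists with no difference. On 5611 genes, matched lists found 100% of lists of 20 genes raised by 0.1 in level, and 5% of unchanged lists fell outside the central 95%. For the replicates, simulated counting noise alone gave a variance ratio of 0.911 and an added replicate SD of 0.1 gave 1.41. Alternatives were other coverage minimums (20, 30 and 50 reads), stricter site thresholds and sites outside runs. Added after the data were examined were sites called in both replicates, 20 or more reads used, sites without spike-ins, the plus strand alone, genes with 5 or more sites and 50 or more reads used for the highest sites. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.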

Results

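Cytosine methylation of messenger RNA was measured by bisulfite sequencing in cultured mouse leukemia cells that carry NRAS together with AE9a, a shortened form of the AML1-ETO fusion protein. Bisulfite turns unmethylated cytosine into uracil, whereas 5-methylcytosine resists, so the methylation level of a position is the fraction of reads that still show cytosine there. The labels name 2 wild-type (WT) libraries and 2 libraries of cells without Tet2, a dioxygenase that oxidises 5-methylcytosine, all from poly(A) RNA. They do not say whether replicates were separate cultures, so the spread between them may be technical. The deposited table used here lists 506952 positions called as methylated in the Tet2 knockout (KO) libraries and, by its name, unique to them. It holds 0 columns with WT values and 0 columns for a single library, so no difference between KO and WT was tested. A listed position is described below as a KO-only site, in the authors' sense; whether it was absent from WT was not checked here, on either strand. The design text plans 70000000 reads per sample, and the library totals were not used here. Coverage at the listed sites ran from 10 to 721 reads with a median of 18 and quartiles of 13 and 25, and the level rested on a median of 12 reads.

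The first question is which transcripts carried sites listed for the KO cells. Tet2 itself had 1 site, at position 133464345 on the minus strand of chromosome 3 (mm10), inside the gene span from 133463677 to 133545136. Its level was 0.273, from 3 unconverted reads of 11 used (Wilson 95% interval 0.0975 to 0.566), with 21 reads covering it. The deleted part of Tet2 is not given in the sources used here, so this site is no check of the knockout. Tspan13, which encodes a tetraspanin, had 1 site at position 36015082 on chromosome 12, with a level of 0.2 from 2 of 10 reads (Wilson interval 0.0567 to 0.510). The chemokine receptor gene Cxcr4 and Ybx1, which encodes an RNA-binding protein, had 0 listed sites. A list that holds only positions with a level of at least 0.2 and at least 10 reads sets no upper limit for such genes. Minus-strand genes with a site had a median of 1, against 68 for plus-strand genes. A count of 0 or 1 is therefore not particular to a gene on the minus strand.

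Nsun2, which encodes an RNA cytosine methyltransferase, had 96 sites on chromosome 13 between 69612016 and 69635780, of which 13 were called in both KO replicates. Their median level was 0.571 with quartiles of 0.4 and 0.727, at a median coverage of 21.5 reads. Its highest site, at 69634958, was unconverted in 10 of 10 reads (Wilson interval 0.722 to 1). Alyref, which encodes an mRNA export factor that binds 5-methylcytosine, had 4 sites with levels of 0.2, 0.211, 0.218 and 0.267. The most deeply read of these by reads used, at 120598202 on chromosome 11, kept 12 unconverted reads of 55 (Wilson interval 0.129 to 0.344). Mbd6, a member of the methyl-CpG-binding domain family, had 3 sites with levels of 0.2, 0.2 and 0.294. Tet2, Tspan13, Alyref and Mbd6 are transcribed from the minus strand and Nsun2 from the plus strand.

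KO-only sites fell in a larger share of most gene lists than of all protein-coding genes. The lists of markers of other cell types (lymphocytes, erythroid cells and megakaryocytes, and stroma) had smaller shares. Among 21900 protein-coding genes, 34.2% had at least 1 site. Sites were found in 18 of 21 glycolysis genes (85.7%), including Pkm, Pdk1 and the lactate transporter gene Slc16a1. Ribosomal protein genes had sites in 55 of 78 members (70.5%), such as Rpl28, Fau and Rplp0, and translation factor genes in 28 of 37 (75.7%), such as Eif1, Eif3b and Eif4b. Markers of T and NK cells had sites in 1 of 15 genes, Nkg7, and markers of B cells in 0 of 11.

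By two-sided Fisher's exact test against the other protein-coding genes, with Benjamini-Hochberg adjustment over 16 lists, 13 lists passed 0.05, of which 11 were higher and 2 lower. The adjusted p was 8.76e-06 for glycolysis, 1.05e-09 for ribosomal proteins and 3.85e-06 for translation factors. It was 0.0331 for T and NK cell markers and 0.0287 for B cell markers. The T and NK call was lost at a coverage minimum of 20 reads (adjusted exact p = 0.0561) and the B cell call at 30 reads (0.0588). Among the alternatives that can change a list, the T and NK call held only for sites outside runs. The test does not correct for expression, and a gene without reads cannot have a site. Counting only genes with 5 or more sites, a choice made after the data were examined, the adjusted p of this exact test was 0.169 for T and NK cell markers and 0.111 for B cell markers, so neither call held. In these settings the lists kept 1 of 15 and 0 of 11 members with a site, while fewer other genes had one. With 5 or more sites a lower share of B cell markers could not pass, as even 0 of 11 did not (unadjusted Fisher's exact p = 0.0765). Under this rule glycolysis genes stood at 11 of 21 (52.4%), translation factor genes at 18 of 37 and ribosomal protein genes at 42 of 78. All of these were past the threshold, against 24.8% of protein-coding genes.

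The immune and adhesion groups that the study's title brings up were also among the lists that passed, as were ribosomal protein, glycolysis and cell cycle genes. Without a correction for expression, passing does not set these groups apart. Homing, adhesion and tetraspanin genes had sites in 25 of 35 members (adjusted Fisher's exact p = 2.27e-05), among them the integrin genes Itgal and Itgam. Antigen presentation genes had sites in 19 of 26 members (adjusted exact p = 0.000154), with examples in H2-Q4, H2-Ab1 and B2m. Immune checkpoint and evasion genes had sites in 19 of 29 members (adjusted exact p = 0.00108), including Vsir, Lgals1 and Cd47, the last encoding a surface protein that restrains phagocytosis. Interferon response genes had sites in 17 of 31 members (adjusted exact p = 0.0287), including Usp18 and Ifi27. With 5 or more sites required, homing genes stood at 16 of 35 and antigen presentation genes at 16 of 26. The interferon call ended at a coverage minimum of 20 reads, where 14 members had a site and the adjusted exact p was 0.124.

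Stem cell and leukemia program genes had sites in 29 of 44 members (adjusted Fisher's exact p = 4.53e-05), including the transcription factor genes Lmo2 and Etv6 and the kinase gene Cdk6. RAS and MAPK signalling genes had sites in 23 of 31 members (adjusted exact p = 2.27e-05), including Shc1, Mapk3 and Dusp5. Cell cycle genes had sites in 26 of 36 members (adjusted exact p = 1.52e-05), including Aurkb, Cdkn1b and Cdc25a. Myeloid granule and differentiation genes had sites in 21 of 33 members (adjusted exact p = 0.00108), including Prtn3, Ncf4 and Mpo, which encodes myeloperoxidase. Counting only genes with 5 or more sites, cell cycle genes stood at 13 of 36 (adjusted exact p = 0.165), granule genes at 13 of 33 (0.108) and stem cell genes at 19 of 44 (0.0164). These lists had 13, 13 and 20 plus-strand genes with a site, close to the counts under this rule. The list drawn up for the 5-methylcytosine machinery had sites in 15 of 29 members and did not pass (adjusted exact p = 0.0587). Its members with sites included Mbd1, Smarcc1 and Nsun5. Erythroid and megakaryocyte markers had sites in 5 of 18 genes (adjusted exact p = 0.630), including Pf4, Vwf and Car2. Stroma markers had sites in 3 of 19 genes (adjusted exact p = 0.153), including Vim. Plus-strand genes made up 73.7% of all genes with a site, 42 of the 55 ribosomal protein genes with a site, 16 of the 19 antigen presentation genes and 13 of the 26 cell cycle genes; these shares were not tested against each other.

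**Figure D1:**
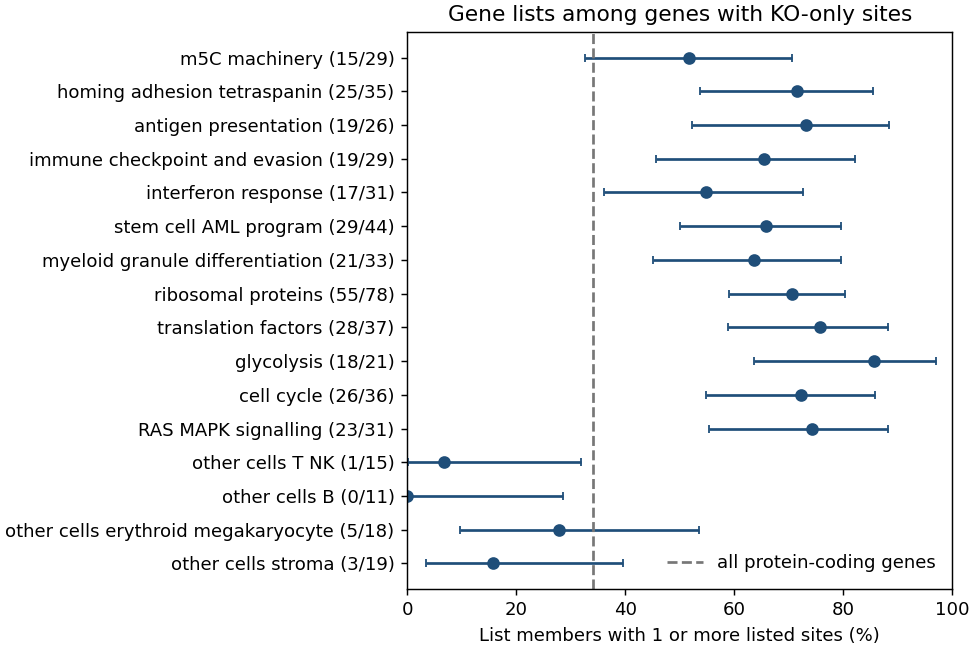
Percent of the members of each gene list that had 1 or more KO-only sites, with exact Clopper-Pearson 95% intervals; the numbers in parentheses are members with a site over members, and the dashed line marks all protein-coding genes at 34.2%. Glycolysis genes lie farthest to the right at 85.7% (52.4% where 5 or more sites are required). The markers of T and NK cells, B cells, erythroid cells and megakaryocytes, and stroma lie left of the line.

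The level of the listed sites differed little between these groups. Only genes with 5 or more sites enter here, 5433 on the plus strand and 140 on the minus strand. Antigen presentation genes had a median gene level of 0.559, against 0.513 in random lists of genes matched on coverage, and stood at percentile 97.7 of 10000 such lists. Ribosomal protein genes had 0.556 against 0.536, at percentile 97.9. Over the 13 lists with enough genes, percentiles ran from 15.8 to 97.9, and neither group passed after Benjamini-Hochberg adjustment (adjusted p = 0.304 for both, two-sided permutation test of list membership within coverage bins). Immune checkpoint genes were lowest, with 0.5 against 0.529.

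The sites with the highest level among protein-coding genes covered by 50 or more reads were unconverted in every read used. Cenpa, which encodes the centromeric histone H3 variant, had such a site at position 30673328 on chromosome 5, with 15 of 15 reads used out of 97 covering (Wilson interval 0.796 to 1). Mdh2, the gene of mitochondrial malate dehydrogenase, had one at 135778726 on chromosome 5, with 18 of 18 reads used out of 76 (0.824 to 1). The others were in Mogs (13 of 13 reads), Tbc1d9b (12 of 12), Arhgef1 (11 of 11), Srebf2 (11 of 11), Riok3 (12 of 12), Ptgir (12 of 12), Slc1a5 (10 of 10) and Arl2bp (10 of 10), all on the plus strand and each called in 1 replicate. Srebf2 encodes a regulator of sterol synthesis and Slc1a5 a glutamine transporter. In all, 124 of 22192 sites with this coverage had a level of 1, so ties were broken by coverage, and most covering reads did not enter these levels.

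With 50 or more reads used for the level, a rule added after the data were examined, the highest site was in Ik, at position 36753513 on chromosome 18, with 53 of 53 reads unconverted (Wilson interval 0.932 to 1). Gnb1, which encodes a G protein beta subunit, followed with 76 of 77 reads (0.987, interval 0.930 to 0.998) at 155491572 on chromosome 4. Ltb4r1, a leukotriene B4 receptor gene, had 58 of 60 reads (0.967, interval 0.886 to 0.991), Pld4 had 53 of 55 and Calu had 67 of 70. In this set, Msl1 and Scd2 had sites called in both replicates, where the authors' mean levels were 0.94 and 0.924 and their listed spread corresponds to SDs of 0.0311 and 0.0269 between the replicates. Scd2 encodes a stearoyl-CoA desaturase. Among the genes named for their lists, Dusp5 was unconverted in 28 of 28 reads used at 53529450 on chromosome 19 (interval 0.879 to 1) and H2-Ab1 in 26 of 26 (0.871 to 1). The intervals cover counting error only. They treat each read used as an independent molecule, which was not checked here, and do not allow for the choice of the highest sites.

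The gene with the most sites was Dync1h1, the dynein heavy chain gene. It had 560 sites with a median level of 0.510, between 110601395 and 110666944 on chromosome 12. Pgs1 had 553 sites (median 0.6), Golgb1, which encodes giantin, 551 (0.455), Cep250 535 (0.529) and Tspoap1, listed as Bzrap1, 532 (0.564). The ubiquitin ligase genes Ubr4 and Huwe1 had 530 and 502 sites, and Abca2, Klc1 and Akap9 had 516, 499 and 493. These 10 genes held 1.10% of the 479042 sites placed in a gene. Over 7756 genes with a site, the median was 43 sites per gene.

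Along genes, sites were densest at the 3' end. The last decile of the RefSeq gene span held 28.8% of 482682 pairs of a site and a gene (exact interval 28.7 to 29.0), in which a site in overlapping genes counts once for each, the ninth decile 14.0%, the second decile 4.71% and the first decile 8.35%. Position within exons, introns and untranslated regions, and the bases around each cytosine, were not analysed here. These shares are not corrected for read coverage along the gene.

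**Figure D2:**
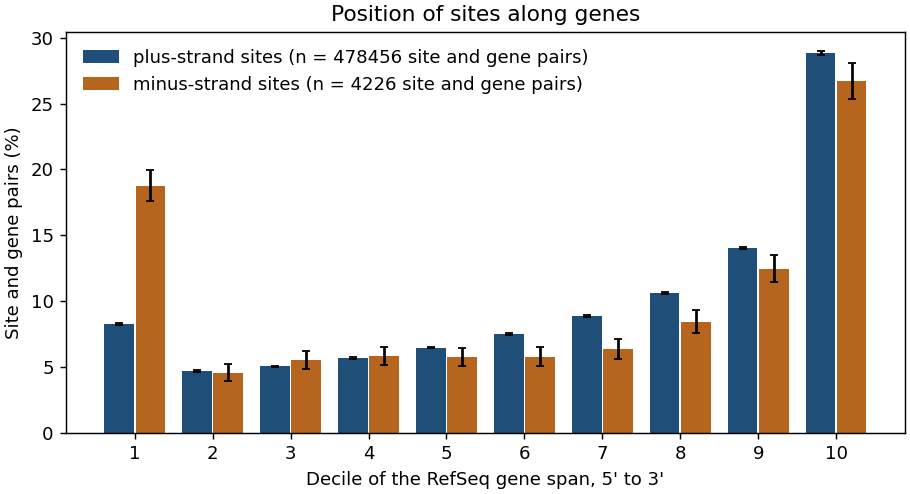
Percent of site and gene pairs in each decile of the RefSeq gene span, from the 5' end to the 3' end, for plus-strand (blue) and minus-strand (orange) sites; error bars are exact 95% intervals. The last decile holds the most on both strands (28.8% and 26.7%), and the first decile holds 18.8% of the minus-strand pairs.

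Genes on the plus strand of the genome carried nearly all of the sites. Plus-strand positions made up 502191 of the 506952 sites (99.1%), and between 98.7% and 99.4% on each of 20 chromosomes, the Y chromosome and mitochondrial genome left out. The 5717 plus-strand genes had a median of 68 sites and the 2039 minus-strand genes a median of 1, and 0 genes had sites on both strands. The median level was 0.531 on the plus strand and 0.231 on the minus strand. Among minus-strand genes, 18 had 10 or more sites. The glucagon gene Gcg led with 228 sites (median level 0.555), and the insulin gene Ins2 followed with 139 (0.623). Others among them, such as Arid1a with 13 sites and Kdm6b with 10, had median levels of 0.3 and 0.25.

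**Figure D3:**
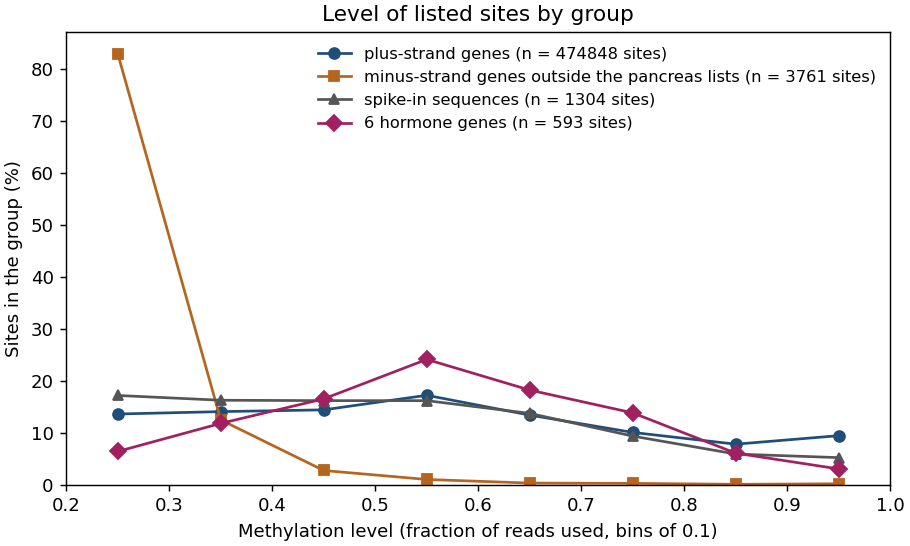
Methylation level of KO-only sites in bins of 0.1 (x axis, fraction of reads used) against the percent of each group's sites (y axis), for sites in plus-strand genes, in minus-strand genes outside the pancreas lists, on spike-in sequences and in 6 pancreatic hormone genes. Of the minus-strand sites 82.9% lie below 0.3, and the other 3 groups spread over the whole range.

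Transcripts of pancreatic hormones were among the most densely covered by sites. The 6 hormone genes Ins1, Ins2, Gcg, Sst, Ppy and Iapp, chosen after their values were seen, held 593 sites with a median level of 0.562. Of these sites, 64.8% were called in both KO replicates, against 14.2% in genes outside the pancreas lists. Ins2, on chromosome 7 between 142678656 and 142679726, had 123 of its 139 sites called in both replicates at a median coverage of 79 reads. Ins1 had 112 sites, 82 of them in both, and Iapp 78 sites, 37 of them in both. Sst and Ppy had 24 and 12 sites, 0 of them in both.

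**Figure D4:**
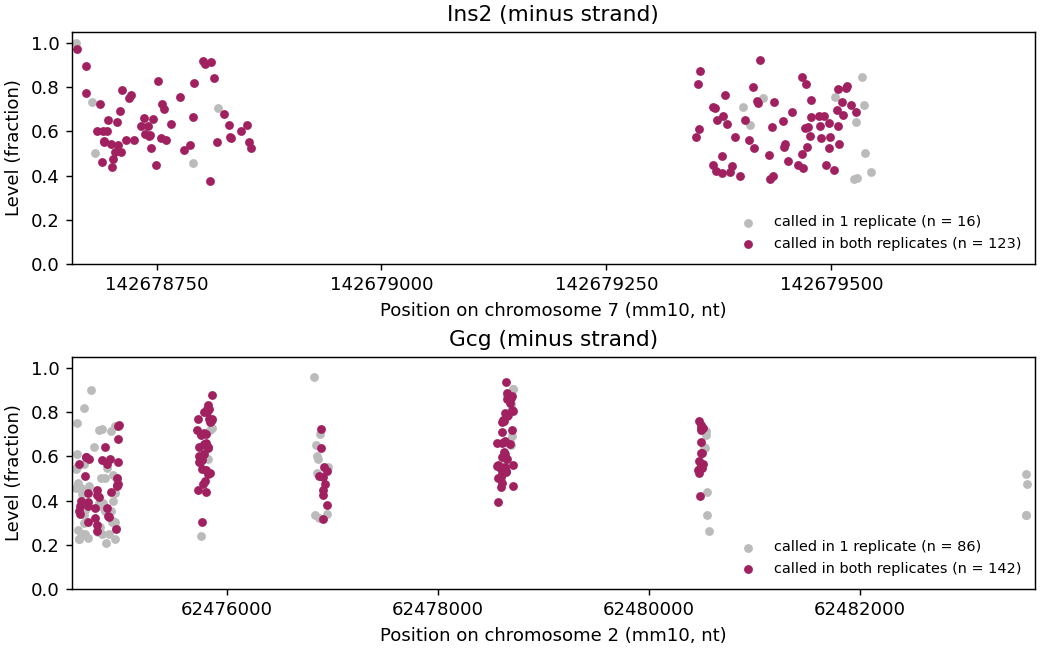
Methylation level (y axis, fraction of reads used) of each KO-only site against its position (x axis, nt, mm10) across the gene span of Ins2 and Gcg; grey points were called in 1 KO replicate and purple points in both. Ins2 has 123 of 139 sites in both replicates and Gcg 142 of 228.

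Sites were also listed on RNA added as a control. Spike-in and other sites alike had to reach a level of at least 0.2, which limits how far their medians can differ. The share of all spike-in cytosines that were listed was not computed. On 47 spike-in sequences, 46 of the ERCC set and 1 Cypridina luciferase, 1304 sites were listed, with a median level of 0.5 against 0.527 for all other sites. At matched coverage the spike-in level differed by -0.038 (bootstrap 95% interval -0.063 to -0.019). Of the spike-in sites, 24.3% were called in both replicates, against 14.2% of the other sites. At 100 or more covering reads the median level was 0.229 over 15 spike-in sites and 0.422 over 2231 other sites. Sites often stood in runs, with another listed site within 10 nt for 70.3% of all sites and for 81.0% of spike-in sites.

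Most sites were called in 1 KO replicate. A call in both replicates was listed for 72227 sites (14.2%) and a call in 1 replicate for 434725 (85.8%). At the shared sites the median absolute difference in level was 0.1, and 10% of sites differed by more than 0.268. The variance between the replicates was 0.844 of that from counting noise alone, where simulated counting noise gave 0.911; only sites that passed the filter in both replicates enter, so this does not measure the full spread between them. Which replicate made a single call is not given, so no test between the replicates was made. Level fell with coverage across sites (Spearman's rho = -0.106; sites are not independent replicates), from a median of 0.545 in the lowest coverage quartile to 0.486 in the highest.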

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

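Both spike-in tests below were written before their results were seen; the comparisons of spike-ins by strand and the counts of sites without a gene label were chosen after.

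Spike-in sequences, which the gene comparisons do not use, held 1304 sites, a signal outside the main measurement with no WT value to set beside it, although these synthetic RNAs are made without 5-methylcytosine. That the sites come from 1 stray library is argued against by the 24.3% of them called in both KO replicates. Cytosines left unconverted may account for them: at matched coverage their level differed from that of other sites by -0.038, within the bound of 0.1 set beforehand. This is a weak check, because both groups hold only sites with a level of at least 0.2. At 100 or more reads the gap was wider than that bound, with a median of 0.229 over 15 spike-in sites against 0.422 over 2231 others, and was not tested. The same source could then add to sites in genes, by an amount that these data do not give, and no biological explanation was tested.

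On most spike-in sequences the listed sites were on the plus strand (1096 against 208), but 7 sequences had more minus-strand sites, among them ERCC-00002 with 55 minus and 1 plus and ERCC-00130 with 41 and 3.

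A gene label was missing for 25812 sites (5.09%), which the gene comparisons therefore leave out.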

How the results depend on the processing

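The alternatives with both replicates required, 20 or more reads used, spike-ins left out, the plus strand alone and genes with 5 or more sites were chosen after the data were examined. No paired analysis was possible because the table used here has no WT values and no values of single libraries. For the same reason leaving out each replicate in turn and the other settings of the KO against WT test were not run, nor were those of sequence context, which need a genome.

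The number of sites was 214033 at 20 reads, 88110 at 30, 22783 at 50, 150787 outside runs, 72227 with both replicates required and 86179 with 20 or more reads used. At 50 reads the median level was 0.432 and 3863 genes had a site. The last decile of the gene held 30.3% of sites at 20 reads, 30.3% at 30, 28.6% at 50, 30.6% outside runs and 29.4% with both replicates; counting each site once left it at 28.8%. The plus strand held 98.5% at 20 reads, 97.6% at 30, 96.2% at 50, 99.3% with at least 3 unconverted reads, 99.4% with the authors' p at most 10% of the highest, 97.8% outside runs, 99.3% with both replicates and 99.1% without spike-ins. The variance ratio was 0.885 at 30 reads. The smaller counts follow from the stricter filters; for the other values the cause was not tested. In the list tests under the 10 alternatives that can change a list, 134 calls stayed on their side of the threshold, 24 were lost and 2 gained; dropping the coverage minimum, which removes no site, or the spike-ins, which hold no gene, cannot change one. The calls lost were in the interferon, granule, cell cycle, T and NK cell and B cell lists, and those gained, at 20 reads, were in the 5-methylcytosine machinery (adjusted exact p = 0.0299) and stroma lists (0.0180). The T and NK cell and B cell lists kept 1 and 0 members with a site under every alternative, so their calls were lost without a change in their members. The plus strand alone and genes with 5 or more sites keep largely the same genes, so these alternatives are not independent of each other. At a median of 12 reads used, a level of 0.5 is known only coarsely, and the 85.8% of sites with a single call have no replicate SD.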

Other observations

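The tests of both strand explanations, of stray calls, of 1 KO library alone and of Tet2 loss below were chosen after the results were seen; that of islet RNA was written before its result, on marker lists written after the hormone genes had been noticed.

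Non-coding transcripts also carried sites. In all, 163 long non-coding RNA genes held 4046 sites (0.845% of the sites placed in a gene). Gm28043, whose sites are labelled Rnf8-cmtr1, had the most with 285, followed by Gm20605 with 158. AU022793 had 136 sites with a median level of 0.482, Mir22hg, the host gene of a microRNA, 91 (0.5), and Snhg16, a snoRNA host gene, 83 (0.615). Rpph1, the RNA component of RNase P, had 24 sites on the minus strand with a median level of 0.487, of which 5 were called in both replicates. The densest windows of 100 nt held 39 sites each, in Ins2 and in Upf3a, a nonsense-mediated decay gene, against a median of 2 over 156116 windows. The next densest held 34 sites in Chaf1a and in Ins1, 33 in another window of Ins2, 32 in Spg20 and 31 in Upf2 and in Gcg.

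The plus strand held 99.1% of sites, although transcription uses both strands. Some genes argue against KO libraries with no callable reads of minus-strand transcripts at all. These 6 genes, Gcg, Ins2, Rpph1, Sst, Ppy and Ctrb1, had 10 or more minus-strand sites and a median level of at least 0.4. All but Rpph1 are on the pancreas lists, and where their reads come from stays open. For transcripts of the leukemia cells themselves only Rpph1 speaks, so a lack of such reads stays open there. Open is that minus-strand sites of genes used in these cells may have been called in WT as well and so left out, whereas plus-strand sites were not (for instance if plus-strand WT calls were missing from the comparison), and then the 502191 plus-strand sites need not be specific to the KO. Pancreas genes, little used in leukemia cells, go both ways. The minus strand held 403 of 593 sites in the 6 hormone genes, through which the pattern was noticed, and 29 of 38 in the exocrine list. Of those 29, 16 lay in Cela1 at a median level of 0.2, near the 0.214 of minus-strand sites outside the pancreas lists. In the other endocrine genes the minus strand held 1 of 22 (4.55%), against 0.786% in genes outside these lists. A gene's strand fixes all its sites, and the 22 sites lie in 3 genes, so these values do not decide, and WT values were not used here.

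Hormone genes of the pancreas were the other pattern that stood out. That 1 KO library alone carried these reads is argued against for Ins1, Ins2, Gcg and Iapp, where 384 of 557 sites (68.9%) were called in both replicates, but stays open for Sst and Ppy, with 0 of 36 (0%), and for Ttr (0 of 13) and Chga (0 of 8). RNA or reads of islets in the KO libraries stay open. The share of the endocrine list set beforehand for this was not reached, with 8 of 20 genes (40%, exact interval 19.1 to 63.9) at 5 or more sites. Beyond the 6 hormone genes, 14.3% lay under the bound set beforehand against it. Both intervals span their bounds, so neither share decides. Stray calls that any silent gene can show stay open too. In Ins1, Ins2, Gcg and Iapp the 68.9% called in both replicates stands against 14.2% in genes outside the pancreas lists. Median coverage was 53, 79, 54 and 26 reads in these genes, against 18 over all sites. In Sst and Ppy it was 16 and 19 reads. The hormone genes were chosen after their values were seen, so these gaps do not test stray calls. Beyond the 6 hormone genes, 2 of 14 endocrine genes (14.3%, exact interval 1.78 to 42.8), Ttr with 13 sites and Chga with 8, had 5 or more sites, against 3 of 20 in the exocrine list and 5 of 78 genes of liver (1 of 18), brain (2 of 20), muscle and heart (2 of 20) and kidney and intestine (0 of 20); the 14 are too few to tell from the 78 (two-sided Fisher's exact p = 0.288). A switching on of the hormone genes by loss of Tet2 cannot be told apart from RNA or reads of islets, because the table has 0 columns with WT values.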
